A study of Homo sapiens with 5 samples.

How the data were processed

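ZBTB7A ChIP-seq was performed in VCaP cells with an R&D Systems antibody and ThruPLEX libraries, per the labels. Vehicle or 10 nM DHT was given for 4 hours in medium with 5% hormone-depleted serum, and routine culture was in 10% full serum. The 5 libraries fall into 3 groups by the culture condition in the labels: CSS (2 libraries), DHT (2) and FBS (1). The treatment text in the labels is the same for all 5 libraries, so that the FBS cells received no DHT was taken from the culture condition and the series design. The data used were 3 peak lists in narrowPeak format, 1 per condition. The labels name the same list for both CSS libraries and the same list for both DHT libraries. How the libraries were combined is not given in the sources used here, and no values per library were used.

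Per the submitters' processing notes, the tools were BWA 0.7.2-r351, SAMtools 0.1.18 and MACS2 2.0.10.20131216, and the build was hg19 (GRCh37). The control library, the q-value threshold, and the filters on duplicate and multiply mapped reads are not given in the sources used here. The lowest −log10 q in the lists was 1.33 in CSS, 1.31 in DHT and 1.31 in FBS. Each peak's fold enrichment is a ratio over background deposited by the authors, in the format's signal column. The −log10 q of each peak is also deposited, and the score deposited by the authors equals the whole part of 10 times that value for 100% of peaks in each list. The narrowest peaks were 191 bp in CSS, 198 bp in DHT and 215 bp in FBS, and 24.1 to 26.2% of peaks lay within 2 bp of that minimum. Fold enrichment and q-values depend on the depth of each library and of its control, so they were used only to describe, rank or filter peaks within a list. The lists hold no read totals, so depth is unknown, and a longer list can come from a deeper library as well as from more binding.

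Coordinates were kept as deposited on hg19 and are written with a first base of 1. A peak had a partner in another list where the peaks overlapped by at least 1 bp. Shares have exact 95% Clopper-Pearson intervals. Ratios of shares between lists have exact conditional binomial intervals, and the difference between shares of unshared peaks has a Newcombe interval. All cover counting error only. The chance level of overlap was the mean of 100 random placements of the peaks on the same chromosomes, and of 100 sets of shifts of 10 to 100 kb. Peaks were ranked by −log10 q within a list and divided into 10 equal parts. The distribution over chromosomes used chromosomes 1 to 22, X and Y. Arms were split at the largest stretch of at least 1 Mb without a peak in any list, and windows of 1 Mb were counted by summit. With 1 list per condition, no test between conditions was made. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap code was tested on simulated data: among CSS and DHT positions with planted partners, between 99.97% and 100% of the planted partners were recovered. These partners were shifted copies that overlapped by construction, so this checks the code only. Of the peaks without a planted partner, between 0.332% and 1.75% were called as having one. The counts of the code equalled those of bedtools 2.31.1 for 6 of 6 pairs of lists.

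Peak counts, overlaps between lists, ranks of unshared peaks, shares per chromosome and the rule for named regions were planned before the data were examined. Chromosome arms, 1 Mb windows, merged regions, summit distances and FBS partners of CSS-only and DHT-only peaks were not named in that plan. Without an annotation of the build, the rule named the 5 peaks with the highest fold enrichment in each list and the 3 DHT-only and 3 CSS-only peaks with the highest −log10 q in their own list. Chromosomes, arms and windows were named after their values were seen. Genomic location of peaks, motif words at summits, promoter occupancy of gene lists, and gene lists gained or lost with DHT had been planned for the case that an hg19 sequence and annotation could be used. The gene table used here is on another build, GRCh38, and coordinates were not converted, so these comparisons were not run and the gene lists have no result. Other settings chosen at that point were a −log10 q of at least 5 or 10, a fold enrichment of at least 5, chromosomes 1 to 22 and X only, an overlap of at least 50% of both peaks, summits within 100 bp, peaks within 500 bp, equal numbers of top peaks from every list, and ranking by fold enrichment. Local shifts, the restriction of overlaps to chromosomes 1 to 22 and X, the stricter thresholds for FBS partners of unshared peaks, equal numbers of top peaks for the distribution over chromosomes, and leaving out a window of chromosome X were added after seeing the data.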

Results

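ZBTB7A, a zinc finger transcription factor of the BTB family also known as Pokemon or LRF, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in VCaP cells. VCaP is an established prostate cancer line that expresses the androgen receptor and carries a fusion of the TMPRSS2 and ERG genes. Cells were kept in hormone-depleted serum and given vehicle (CSS, 2 libraries) or 10 nM of the androgen DHT (DHT, 2 libraries) for 4 hours, or were grown in full serum (FBS, 1 library). The labels attach the same treatment text to the FBS library as to the others, so FBS was taken as full serum without added DHT from its culture condition and the series design, and comparisons with FBS rest on that reading. Each condition is represented by 1 peak list, so no spread between replicates could be measured and no p-value between conditions is given. Intervals are exact 95% intervals unless another method is named, and they cover counting error only. The lists hold no read totals, so the depth of each library is unknown. Positions are on the hg19 build, as the lists give them. No hg19 gene annotation was used, so regions are given by position and are not assigned to genes.

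ZBTB7A peaks were called at 37782 places in CSS, 34120 in DHT and 124868 in FBS. The FBS list was 3.30 times as long as the CSS list and 3.66 times as long as the DHT list, while the CSS list was 1.11 times as long as the DHT list. With a fold enrichment of at least 5, the order of CSS and DHT turned, at 23893 and 24401 peaks. Peaks covered 12.0 Mb in CSS, 10.8 Mb in DHT and 39.3 Mb in FBS. They were narrow in each list, with median widths of 239 bp in CSS, 249 bp in DHT and 258 bp in FBS. Peaks of at least 1000 bp were few, 707 in CSS, 464 in DHT and 1222 in FBS. The fold enrichment and the q-value of each peak are the authors' and describe it within its own list only. Median fold enrichment was 5.58 in CSS, 5.70 in DHT and 4.56 in FBS. Strong peaks, with a −log10 q of at least 10, numbered 5485 in CSS (14.5% of the list), 4040 in DHT (11.8%) and 6140 in FBS (4.92%). At this threshold the FBS list differed far less in length from the others than over all peaks. A fixed q-value need not mark equal strength in lists of unknown depth. At a fold enrichment of at least 5, FBS had 40086 peaks.

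The peaks with the highest fold enrichment were mostly called in each of the 3 lists. No regions were removed here for repeated sequence or background, so a high rank in each list does not by itself show binding. A peak on chromosome 3 from 196625524 to 196625909 ranked first by fold enrichment in each list, at 30.2 in CSS, 29.1 in DHT and 23.1 in FBS. The peak ranked next in CSS and in DHT lay on chromosome 2 from 33141175 to 33141655 (22.2 in CSS and 21.3 in DHT), and its FBS partner had a fold enrichment of 14.4. A peak on chromosome 1 from 91852810 to 91853241 was among the 5 highest of each list, at 20.6 in CSS, 18.9 in DHT and 21.3 in FBS. The other peaks among the CSS leaders follow. The peak on chromosome 13 from 112170147 to 112170657 (19.9 in CSS, 14.4 in DHT) had no FBS partner, and the peak on chromosome 3 from 112275087 to 112275451 (19.02 in CSS, 10.16 in DHT) had an FBS partner with a fold enrichment of 4.76. The DHT leaders also included chromosome 17 from 79935592 to 79936001 (19.3 in DHT, 17.2 in CSS, 13.0 in FBS) and chromosome 13 from 110141256 to 110141775 (18.99 in DHT, 16.5 in CSS, 8.78 in FBS). Among the FBS leaders, the peak on chromosome X from 66300022 to 66300435 had a fold enrichment of 20.4 and no partner in CSS or DHT. The peaks on chromosome 22 from 18717969 to 18718353 (19.3 in FBS, 18.1 in CSS, 15.1 in DHT) and on chromosome 13 from 110076338 to 110076725 (18.96 in FBS, 9.53 in CSS, 10.0 in DHT) had partners in both other lists.

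The first comparison asked how ZBTB7A binding differed with and without DHT in hormone-depleted serum. Nearly all of the strongest peaks were called in both conditions, and the peaks called in 1 condition only lay mostly among the weaker ones. Of the CSS peaks, 21455 (56.8%, 56.3 to 57.3%) overlapped a DHT peak by at least 1 bp. Of the DHT peaks, 21818 (63.9%, 63.4 to 64.5%) overlapped a CSS peak. Random placement of the peaks on the same chromosomes gave 0.743% and 0.827%. Shifts of 10 to 100 kb from each peak's own position gave 1.07% and 1.19%. Each list was then divided into 10 equal parts by q-value. In the highest part, 97.0% (96.4 to 97.5%) of CSS peaks and 95.3% (94.5 to 96.0%) of DHT peaks had a partner in the other list. In the lowest part the shares were 20.5% (19.3 to 21.9%) and 36.7% (35.0 to 38.3%). The rise between them was not unbroken: the CSS share fell from 33.9% to 30.3% between parts 2 and 3, and the DHT share from 47.7% to 43.6% between parts 3 and 4. All 707 CSS peaks and all 464 DHT peaks of at least 1000 bp had a partner, with lower bounds of 99.5% and 99.2%, but only 42.1% and 36.2% of them had one with a summit within 100 bp.

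The 16327 CSS peaks without a DHT partner had a median rank at percentile 27.9 of their list by q-value, and the 12302 DHT peaks without a CSS partner at percentile 31.3 of theirs. Their median fold enrichments were 4.78 and 5.03, against 6.37 and 6.18 for the partnered peaks of the same lists. Few of the unpartnered peaks were strong: 263 in CSS and 219 in DHT had a −log10 q of at least 10. The 3 DHT-only peaks with the highest −log10 q lay on chromosome 10 from 9972940 to 9973205 (−log10 q of 20.2, fold enrichment 13.7), on chromosome 10 from 55958226 to 55958518 (19.01, 13.2) and on chromosome 1 from 12421443 to 12421739 (18.5, 13.1). They ranked 184, 257 and 287 in the DHT list by q-value. The 3 CSS-only peaks with the highest −log10 q lay on chromosome 9 from 69708525 to 69708843 (−log10 q of 20.6, fold enrichment 7.30), on chromosome 1 from 59762290 to 59762565 (20.1, 12.9) and on chromosome 9 from 140288549 to 140289085 (20.0, 9.88). They ranked 742, 827 and 833 in the CSS list. None of these 6 peaks had a peak of the other list within 500 bp. An FBS peak was present at 4 of them, and was missing at 55958226 to 55958518 on chromosome 10 and at 140288549 to 140289085 on chromosome 9. In the FBS list of 124868 peaks, the FBS peaks at the DHT-only sites ranked 87204 (−log10 q of 3.52) and 124525 (1.86). Those at the CSS-only sites ranked 24993 (6.13) and 16031 (7.25).

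Sites shared by CSS and DHT had nearby summits, at a median distance of 62 bp, and 66.5% of the shared CSS peaks had a DHT summit within 100 bp. When only summits within 100 bp counted as shared, the shares fell to 37.8% of CSS peaks and 41.8% of DHT peaks, and among peaks with a −log10 q of at least 10 they were 95.2% and 94.6% by overlap. The control library of the CSS and DHT lists is not given in the sources used here, so background common to both lists is part of the overlap to an unknown extent.

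**Figure D1:**
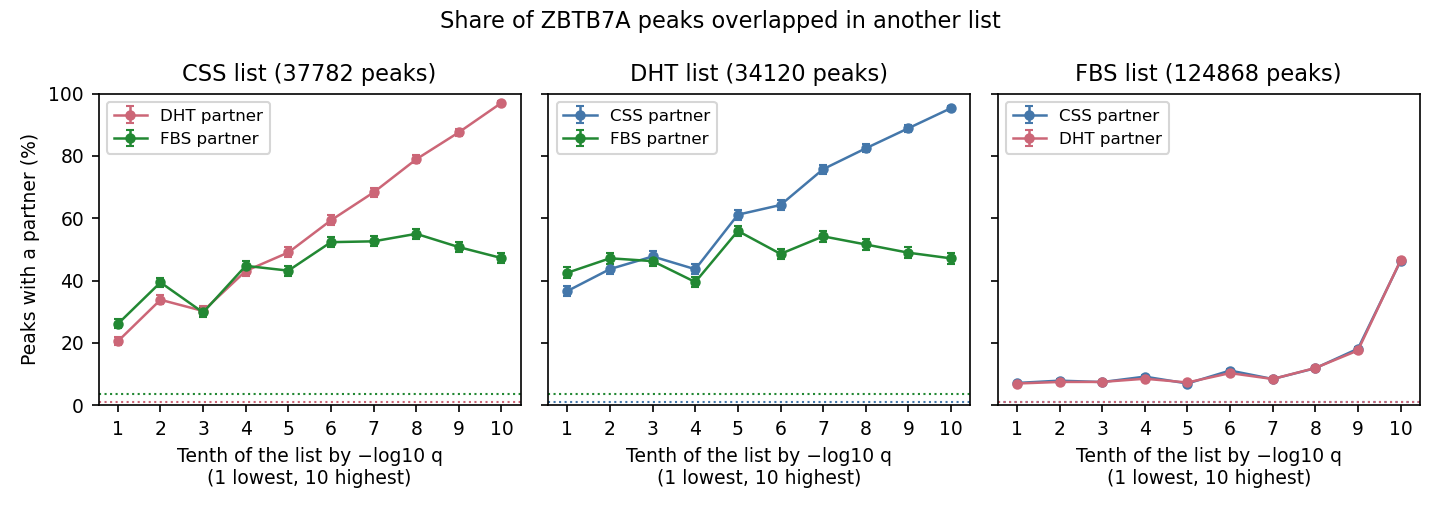
Percent of peaks with an overlapping peak in another list (vertical axis) in 10 equal parts of the CSS, DHT and FBS lists ordered by −log10 q (horizontal axis, 10 highest), with exact 95% intervals as bars and the mean of 100 local shifts as dotted lines. CSS and DHT peaks with a partner in each other reach 97.0% and 95.3% in the highest part. CSS peaks with an FBS partner go from 26.1% in the lowest part to 55.0% in part 8, with a fall from 39.4% to 29.8% between parts 2 and 3. They stand at 47.2% in the highest part, where the DHT value is 47.1%.

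The next comparison set full serum against hormone-depleted serum with or without DHT. Most FBS peaks were at places with no CSS or DHT peak, and many of the strongest CSS and DHT sites had no FBS peak although the FBS list was the longest. After merging overlapping peaks, 151256 regions held a peak in at least 1 list. Of these, 11600 (7.67%) held a peak in each of the 3 lists, 9033 in CSS and DHT only, 4066 in CSS and FBS only, and 3943 in DHT and FBS only. A further 11452 regions were seen in CSS alone, 7720 in DHT alone and 103442 (68.4%) in FBS alone.

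**Figure D2:**
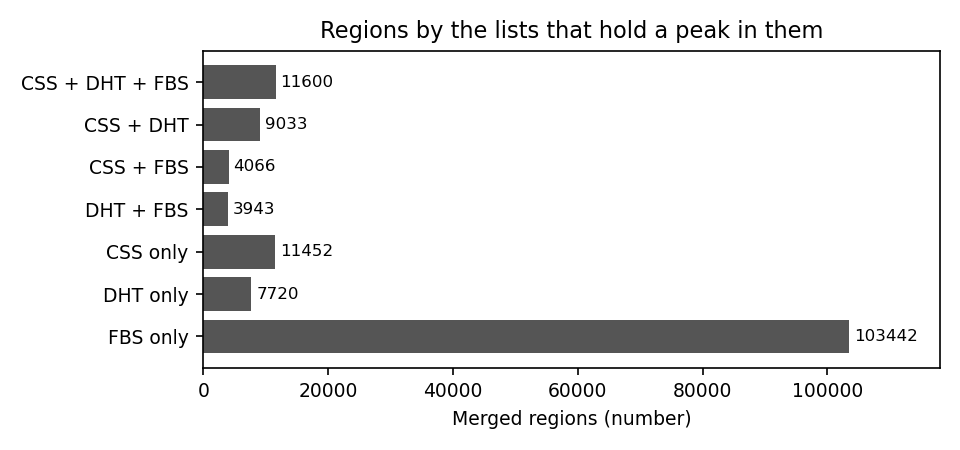
Number of merged regions (horizontal axis) by the lists that hold a peak in them (vertical axis). The 103442 regions seen in FBS alone make up 68.4% of the 151256 regions, and 11600 were seen in each of the 3 lists.

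An FBS partner was present for 44.1% (43.6 to 44.6%) of CSS peaks and 48.2% (47.6 to 48.7%) of DHT peaks, against 3.56% and 3.63% after local shifts. In the other direction, 17.2% (17.0 to 17.4%) of FBS peaks had a partner in CSS or DHT, against 1.43% after local shifts. The share of CSS peaks with an FBS partner went from 26.1% in the lowest part of the list to 55.0% in part 8 and was lower again in the highest part. This rise was broken by falls from 39.4% to 29.8% between parts 2 and 3 and from 44.7% to 43.2% between parts 4 and 5. The DHT share lay between 39.5% in part 4 and 55.9% in part 5. The share with an FBS partner was 47.2% (45.6 to 48.8%) in the highest 10% of CSS peaks and 47.1% (45.4 to 48.8%) in the highest 10% of DHT peaks. Among peaks of at least 1000 bp, 56.3% (52.5 to 59.99%) of CSS peaks and 55.2% (50.5 to 59.8%) of DHT peaks had an FBS partner. Strong FBS peaks were more often shared: 54.1% of the highest 10% of the FBS list and 91.7% (90.05 to 93.2%) of FBS peaks of at least 1000 bp had a CSS or DHT partner. Summits of FBS peaks lay farther away, at a median of 111 bp from the DHT summit, and 44.7% of CSS peaks with an FBS partner had an FBS summit within 100 bp.

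These shares depended on what counted as shared. With an overlap of at least 50% of both peaks, 20.9% of CSS peaks, 23.2% of DHT peaks and 9.40% of FBS peaks kept a partner, and with summits within 100 bp 19.7%, 22.3% and 9.36% did. With as many top peaks from every list as the shortest list holds, the shares were 26.7%, 27.6% and 31.8%, with the top 5000 peaks 14.6%, 14.2% and 20.2%, and 67.1% of FBS peaks with a −log10 q of at least 10 had a CSS or DHT partner. In the highest 10% of the lists, the shares of CSS, DHT and FBS peaks were 24.3%, 29.2% and 29.1% with the 50% overlap and 21.7%, 24.5% and 29.7% with summits within 100 bp, and among peaks of at least 1000 bp they were 10.6%, 13.8% and 31.01%, and 12.2%, 8.84% and 40.7%.

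DHT-only peaks were found in full serum more often than CSS-only peaks, but not among peaks well above the calling threshold. An FBS partner was present for 37.2% (36.4 to 38.1%) of DHT-only peaks and 29.9% (29.2 to 30.6%) of CSS-only peaks, a difference of 7.39 percentage points (Newcombe interval 6.28 to 8.49). Among peaks with a −log10 q of at least 5, the shares were 41.1% and 41.0%, and the difference was 0.0195 points (-2.21 to 2.25). At a −log10 q of at least 10 it was -1.49 points (-10.0 to 7.17). Peaks shared by CSS and DHT had an FBS partner in 55.0% of cases in the CSS list and 54.3% in the DHT list, above both classes of unshared peaks.

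The last comparison was of how the peaks of each list were spread over the chromosomes. CSS and DHT peaks had nearly the same distribution, while FBS peaks were concentrated on some chromosome arms and sparse on others. The share of the DHT list on an autosome divided by that of the CSS list lay between 0.935 and 1.04 over the 22 autosomes, and 0 of the 22 intervals excluded 1. It was 0.956 (0.878 to 1.04) on chromosome X and 0.865 (0.725 to 1.03) on chromosome Y. For FBS against CSS the ratio ranged from 0.590 (0.544 to 0.639) on chromosome 16 to 1.48 (1.41 to 1.57) on chromosome 8, and 18 of the 22 intervals excluded 1. Chromosome 21 also held a larger share of the FBS list (1.41, 1.29 to 1.55). Chromosomes 19 (0.641, 0.602 to 0.684), 22 (0.718, 0.657 to 0.786), X (0.532, 0.494 to 0.572) and Y (0.378, 0.324 to 0.441) held smaller shares. Peaks are not independent of their neighbours, and the intervals are not adjusted for the number of chromosomes. Among peaks with a −log10 q of at least 10, the ratios for chromosomes 16, 19 and X became 0.359, 1.06 and 0.942. These are given without intervals, so a turn in direction for chromosome 19 is not shown.

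By arm, the excess on chromosome 8 lay on its long arm. Arms and windows named here were chosen after their values were seen. The FBS to CSS ratio was 1.78 (1.67 to 1.89) on 8q and 0.718 (0.643 to 0.803) on 8p. Smaller excesses were seen on 21q (1.44, 1.31 to 1.58), 20p (1.31, 1.17 to 1.47) and 3p (1.25, 1.17 to 1.33), and the lowest ratios were on Xq (0.5005, 0.455 to 0.551) and 19p (0.528, 0.475 to 0.587). The corresponding DHT to CSS ratio on 8q was 0.992 (0.913 to 1.08). Although 8p had a low ratio as an arm, its window from 38000001 to 39000000 held 154 FBS and 21 CSS peaks (2.19, 1.38 to 3.63).

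**Figure D3:**
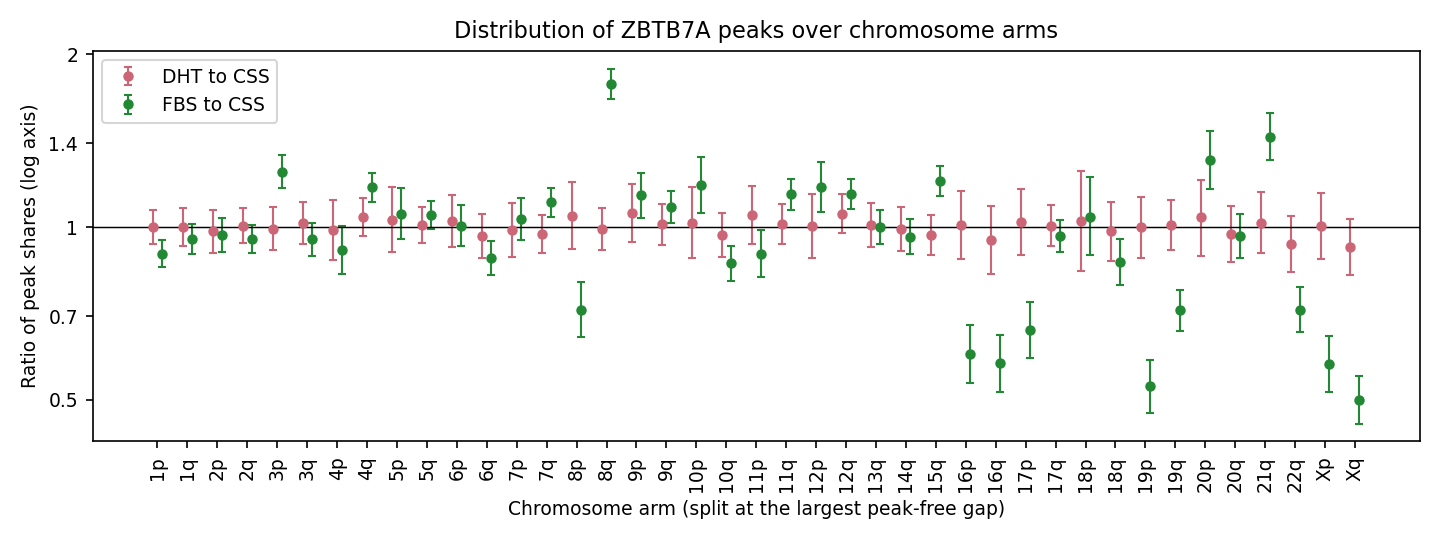
Share of a list's peaks on each chromosome arm divided by the share of the CSS list (vertical axis, log scale) for DHT and FBS, with exact 95% intervals as bars. DHT points lie close to 1, while FBS points range from 0.5005 on Xq to 1.78 on 8q.

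Over 2916 windows of 1 Mb, a window held a median of 11 CSS, 10 DHT and 39 FBS peaks. Across windows, which are not independent replicates, Spearman's rho was 0.880 between CSS and DHT, 0.678 between CSS and FBS and 0.707 between DHT and FBS. The window with the most FBS peaks lay on chromosome 13 from 110000001 to 111000000, with 279 FBS, 23 CSS and 27 DHT peaks. The adjoining window from 111000001 to 112000000 held 247 FBS peaks and was also rich in CSS (47) and DHT peaks (54), with a ratio of FBS to CSS shares of 1.57 (1.14 to 2.19). On chromosome 6 from 20000001 to 21000000 there were 228 FBS, 15 CSS and 20 DHT peaks. On chromosome X from 66000001 to 67000000 there were 191 FBS peaks against 5 in CSS and 6 in DHT, a ratio of FBS to CSS shares of 11.4 (4.80 to 35.5). That window held 136 of the FBS peaks on chromosome X with a −log10 q of at least 10, and without it the ratio for chromosome X at this threshold was 0.267 (0.192 to 0.366) in place of 0.942. The stretch of chromosome 6 from 30000001 to 33000000 held few FBS peaks, 15 against 66 in CSS and 59 in DHT. Between DHT and CSS, the window on chromosome 8 from 7000001 to 8000000 held 29 DHT and 11 CSS peaks (ratio of shares 2.91, 1.41 to 6.46), and the window on chromosome 4 from 3000001 to 4000000 held 9 and 24 (0.414, 0.169 to 0.923). These were among the most uneven of 2916 windows and their intervals are not adjusted for that choice.

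**Figure D4:**
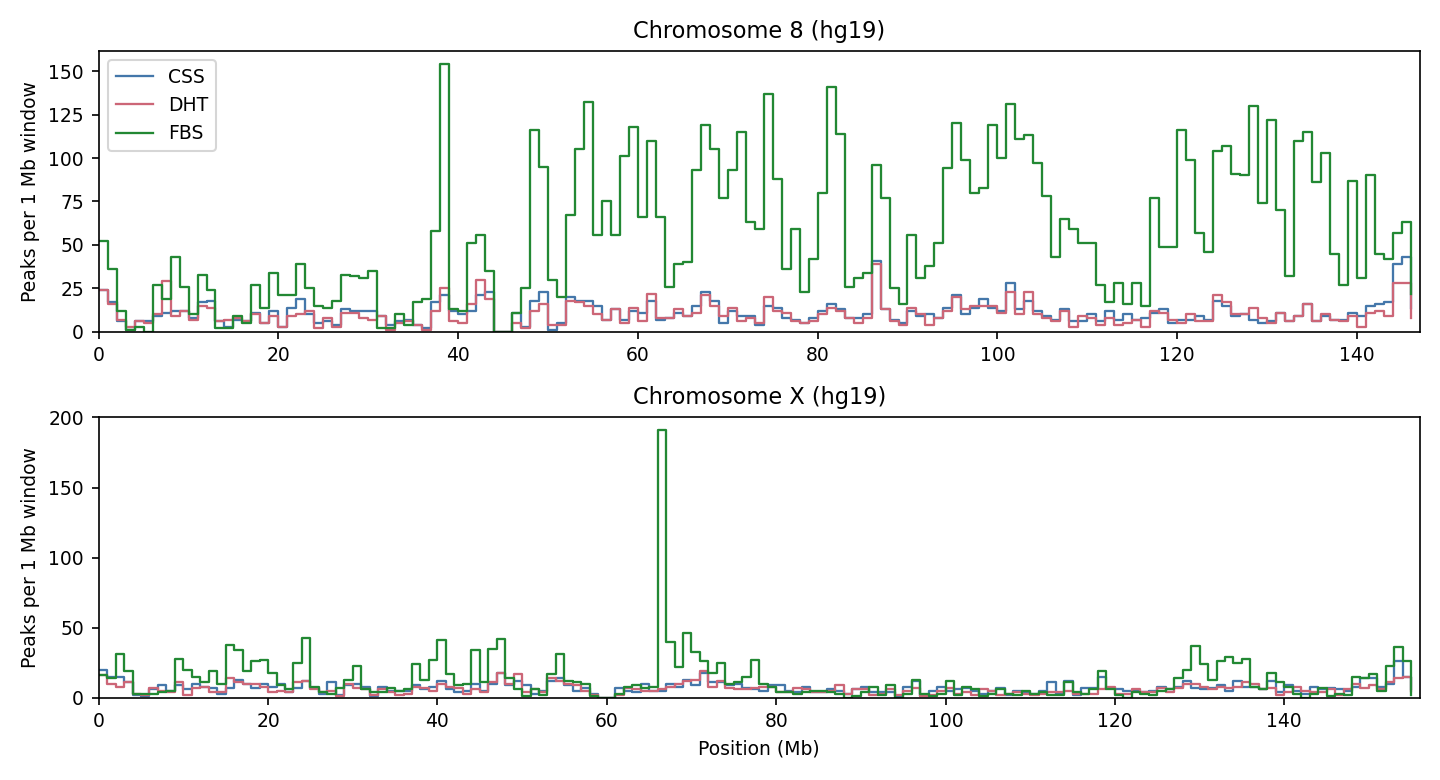
Number of peaks per 1 Mb window (vertical axis) along chromosomes 8 and X (horizontal axis, position in Mb on hg19) in the CSS, DHT and FBS lists. FBS peaks are dense along the long arm of chromosome 8, and on chromosome X 1 window holds 191 of the 2060 FBS peaks.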

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

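The counts in this part are of peaks on sequences other than the assembled nuclear chromosomes. They are included in the peak numbers and overlaps above but not in the comparison over chromosomes, and are listed for that reason. Each count is above 3, the cut-off used for listing. This is a low bar that tests no expected count and does not tell binding from background. No test of an explanation was made for them.

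Alternate haplotype sequences of the assembly held 579 CSS peaks (1.53% of the list), 494 DHT peaks (1.45%) and 280 FBS peaks (0.224%). Most of these, 541 in CSS, 455 in DHT and 203 in FBS, were on alternate versions of a part of chromosome 6. The unplaced contig gl000220, which carries ribosomal RNA gene sequence, held 23 CSS, 27 DHT and 57 FBS peaks. The mitochondrial genome held 7 CSS, 4 DHT and 12 FBS peaks, with a −log10 q of up to 149 in FBS.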

How the results depend on the processing

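Each alternative changed 1 choice at a time unless a pair is named. Restricting overlaps to chromosomes 1 to 22 and X, the thresholds for FBS partners of unshared peaks, equal numbers of top peaks for the distribution over chromosomes, and leaving out the X window were chosen after the results were seen. Of the values under alternatives, 32 stayed within the interval or the 1.5-fold range of the reported value, 82 moved beyond it and 2 turned in direction. No paired analysis was possible because the CSS and DHT libraries, which share numbers in the labels, are represented by 1 list per condition, and for the same reason no library could be left out. The alternatives for genomic location, motif words and gene lists were not run, since no hg19 sequence or annotation was used. Unless the construction of an alternative shows the cause (fewer peaks, a stricter overlap), the cause was not tested. Library depth is unknown and limits any reading of the list lengths.

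Peak counts at a −log10 q of at least 5 were 18404 in CSS, 18222 in DHT and 51063 in FBS. At 10 they were 5485, 4040 and 6140. At a fold enrichment of at least 5, CSS had 23893, DHT 24401 and FBS 40086, so that DHT had more peaks than CSS. The following shares are given in the order CSS peaks with a DHT partner, DHT with CSS, CSS with FBS, DHT with FBS, and FBS with CSS or DHT. They were 43.8, 48.5, 20.9, 23.2 and 9.40% with an overlap of at least 50% of both peaks, and 37.8, 41.8, 19.7, 22.3 and 9.36% with summits within 100 bp. They were 60.2, 62.1, 35.8, 34.3 and 17.5% with a −log10 q of at least 5 in both lists, and 95.2, 94.6, 47.9, 47.1 and 67.1% with at least 10 in the first list. With as many top peaks as the shortest list they were 60.7, 62.0, 26.7, 27.6 and 31.8%, with the top 5000 peaks 52.7, 53.5, 14.6, 14.2 and 20.2%, and with peaks within 500 bp counted as shared 62.3, 68.8, 50.9, 54.8 and 21.2%. On chromosomes 1 to 22 and X, 44.8% of CSS and 48.8% of DHT peaks had an FBS partner. Among the highest 10% of each list by q-value, the CSS and DHT shares shared with each other were 87.1 and 88.0% with the 50% overlap, and 66.6 and 71.6% with summits within 100 bp. Wide peaks kept a partner in 78.4% (CSS) and 94.6% (DHT) of cases with the 50% overlap, and in 42.1 and 36.2% with summits within 100 bp.

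Ranked by fold enrichment, unshared CSS and DHT peaks had a median at percentiles 28.9 and 33.2. The DHT-only minus CSS-only difference in FBS partners was 0.0195 points at a −log10 q of at least 5 and turned to -1.49 points at 10, where its interval included 0. The FBS to CSS ratios at a −log10 q of at least 10 were 1.60 for 8q, 0.942 for chromosome X, 0.359 for chromosome 16 and 1.06 for chromosome 19. The last one crossed 1 but lay close to it and has no interval. With equal numbers of top peaks the ratios were 2.09 for 8q, 0.583 for X, 0.456 for chromosome 16 and 0.647 for chromosome 19, which kept its direction there. Without the window on X from 66000001 to 67000000, the X ratio was 0.484 over all peaks and 0.267 at a −log10 q of at least 10.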

Other observations

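The tests of explanations in this part and the windows named were chosen after the results were seen, while the overlap of at least 1 bp and the ranking by q-value were set before the data were examined. The windows densest in CSS peaks that are named here each held a smaller share of the FBS list than of the CSS list. Choosing windows by a high CSS count favours ratios below 1, and the intervals are not adjusted for that choice. The 2 windows with the most CSS peaks were adjacent, on chromosome 11 from 64000001 to 65000000 with 73 CSS, 61 DHT and 113 FBS peaks (FBS to CSS ratio of shares 0.461, 0.341 to 0.628), and from 65000001 to 66000000 with 68 CSS, 62 DHT and 143 FBS peaks (0.627, 0.466 to 0.850). The end of chromosome 17 from 80000001 to 81000000 held 52 CSS, 39 DHT and 59 FBS peaks, a ratio of 0.338 (0.229 to 0.501). On chromosome 20 from 62000001 to 63000000 there were 53 CSS, 33 DHT and 65 FBS peaks, a ratio of 0.366 (0.250 to 0.536). In contrast, FBS peaks in the window on chromosome X from 66000001 to 67000000 had a median rank at percentile 98.4 of the FBS list, and 2.09% of them had a CSS or DHT partner. With equal numbers of top peaks that window held 174 FBS and 5 CSS peaks. As background, VCaP is known to carry extra copies of the androgen receptor gene, which lies on the proximal long arm of chromosome X; no annotation was used to place it.

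The strongest shared sites were not ranked alike in every list. Of the highest 10% of CSS peaks with a DHT partner, 49.1% had that partner in the highest 10% of the DHT list, and the median partner stood at percentile 89.7. For those with an FBS partner, 40.2% had it in the highest 10% of the FBS list, and the median partner stood at percentile 76.2. These ranks describe the lists and do not measure a change in binding.

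The first pattern weighed is the concentration of FBS peaks on 8q and in single windows. A longer FBS list without regional difference is argued against, since with equal numbers of top peaks the FBS to CSS ratio on 8q was 2.09 (1.94 to 2.25), and the interval excluded 1 on 20 of the 22 autosomes. DNA copy number acting more on the FBS list than on the others, for instance through its control or depth, remains a candidate explanation. The FBS to CSS ratio of neighbouring windows, taken after a constant was added to each count, had a rho of 0.538. The highest of 100 permutations within arms was 0.241. Because the FBS list is longer, the constant lowers this ratio in windows with few peaks. Peak density that is alike in neighbouring windows would thus raise rho without a regional difference, and permutation removes that too. Any factor that varies smoothly along a chromosome would also raise rho, so the value does not single out copy number. The DHT to CSS ratio had a rho of 0.00665. These lists are closer in length, so the constant affects their ratio less, and part of the contrast may come from it. With medians of 11 CSS and 10 DHT peaks per window, counting error weakens that contrast. Binding that differs by region in full serum would give the same neighbour correlation. It stays open, since the condition and its single library cannot be separated here.

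The second pattern is that 47.7% of the highest 10% of CSS peaks with a DHT partner had an FBS partner, although the FBS list was longer. Sparse FBS calling in some regions could not be decided as a cause. In the fifth of windows richest in FBS-only peaks the share was 55.3% (52.5 to 58.2%), so many such peaks lacked an FBS partner even there. That ranking counts only FBS peaks without a CSS or DHT partner, so it need not mark windows where FBS calling was sensitive. The share ranged from 39.9 to 46.8% in the other windows, so sparse calling may contribute in part. Among the 3517 of 3666 such peaks outside alternate and unplaced sequences, chromosome Y and chromosome 6 from 30000001 to 33000000 the share was 47.7%, so the pattern does not come from those sequences, while repeated sequence elsewhere was not examined. A difference in serum, control, depth or preparation between the single FBS library and the others was not tested.

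The third pattern is the peaks called in CSS only or DHT only. Sites near the calling threshold that passed it in 1 list stay open as an explanation. With a threshold of 10 in −log10 q set on both lists, 86.5% (84.8 to 88.1%) of the DHT peaks and 91.5% of the CSS peaks that then lacked a partner had a weaker one below it. This shows what a threshold does within these lists and follows in part from the high partner share of strong peaks, and the lists hold no calls below the deposited threshold with which to decide. There were 263 CSS-only and 219 DHT-only peaks with a −log10 q of at least 10, and no effect of DHT at them can be shown or excluded with 1 list per condition.

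A hypothesis that androgen in full serum brings DHT-only sites into the FBS list could not be decided. The difference between DHT-only and CSS-only peaks was 7.39 points over all peaks. At a −log10 q of at least 5 it was 0.0195 points (-2.21 to 2.25). The peaks kept by that threshold thus showed no excess of FBS partners for DHT-only peaks. The difference lay among weaker peaks, which the threshold leaves out, so its cause there stays open.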
